A study of Mus musculus with 12 samples.

How the data were processed

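Messenger RNA was sequenced from mouse neural cortical stem cells in 12 samples, 4 for each of 3 groups (no EV, mTSC EV and pTGC EV). Per the labels' protocols, RNA was purified with a column kit and libraries were made with a stranded mRNA kit that selects polyadenylated RNA. The deposited counts are whole numbers of read pairs per gene with no normalisation. Per the submitters' processing notes, reads were aligned with STAR 2.7.10b to GRCm39. Per the file headers, read pairs with both ends mapped were counted over the exons of each gene of GENCODE M30 with featureCounts 2.0.3. The command in the file headers sets no strand option, so a read pair was assigned without regard to strand although the kit keeps it, and it counts neither multi-mapping reads nor reads that overlap several genes. Reads from exonic bases shared with another gene were therefore not counted. This was checked for 70 of the named genes, of which 19 had such an overlap, and it covered more than 10% of the exonic bases of 6: Nrarp (79.4%), Rarb (38.4%), Sox21 (18.8%), Ubc (17.5%), Plxna2 (15.4%) and Ccdc78 (10.5%). The submitters' processing notes also name DESeq2, without a version, and no output of it was used here.

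The table held 56691 genes. Gene symbols were added by Ensembl identifier from an older annotation that served for names alone, with 4618 identifiers left without a symbol. Of the 685 list genes, 6 were found under an older symbol and 1 was not found. Coordinates are the outermost exon bounds that the deposited table gives for each gene on GRCm39.

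Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups, which left 19213 genes, and libraries were scaled by TMM. A quasi-likelihood F test with 1 mean per group was fitted to all 12 samples, so that the 3 comparisons shared the estimate of the spread (common biological coefficient of variation 0.0681). P-values are two-sided and were adjusted over all tested genes of a comparison by Benjamini and Hochberg, and a gene passed at an adjusted p below 0.05. Levels are TMM-scaled read pairs of a gene per M (mega) read pairs (CPM), except that summed levels of marker lists were not TMM-scaled. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Camera asks whether the members rank above or below all other tested genes. Adjustment was over the 28 lists with at least 5 tested members, except that lists written after the data had been seen were adjusted together with those 28. Camera with an estimated correlation and fry were run as alternatives. Fry asks whether the members move, on balance, in 1 direction, without comparing them with other genes. The share of mitochondrially encoded counts and other features of the libraries were compared by exact permutation tests, two-sided, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9. The effect of sharing the 4 no EV samples was measured in 100 simulations of unchanged groups and by giving each EV group a separate pair of the controls. In the same simulations, the overlap of as many top-ranked genes as were called was counted, a measure chosen after the data had been seen.

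The comparisons, tests, alternatives, 30 gene lists and the rule for named genes were fixed before the data were examined. The lists, written from textbook knowledge, cover neural cell types, the cell cycle, signalling, stress, metabolism, organelles and markers of trophoblast, fibroblast, microglial and endothelial cells. The lists for trophoblast giant cells and for microglia and macrophages had fewer than 5 tested members and are given as summed levels. Lists of nuclear-retained RNAs, clock genes and heat shock chaperones were written after the data had been seen. The chaperone list also holds the ubiquitin genes Ubc and Ubb. The rule named, for each comparison, up to 8 genes with the largest positive and up to 8 with the largest negative log2 fold change. These had to pass the test, reach 5 CPM in the higher group, have a gene name other than a placeholder, and have all 4 samples of 1 group above all 4 of the other. It added up to 4 passing members of each list with the smallest p, and the most abundant trophoblast and fibroblast markers whatever their p. The text describes a subset, taken in rank order within each part.

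The alternatives were DESeq2's size factors, no filter, a filter of 1 CPM in 4 samples, DESeq2 1.42.0, limma-voom, only the 2 groups compared, the replicate number as a block, and leaving out each library in turn. After the data had been seen, the level of nuclear-retained RNA was added as a covariate, and no EV replicate 3 was also left out for pTGC EV against mTSC EV.

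The analysis was tested on simulated data with 200 changed genes. It called 50.8% of genes changed 1.25-fold, 50.0% of those changed 1.5-fold and 79.7% of those changed 2-fold. At a mean of at least 5 CPM these shares were 78.6%, 100% and 100%. Of 123 genes called, 6 had not been changed, and no gene was called in a simulated comparison without changes. Libraries held 45.2 to 58.3 M assigned read pairs. Read pairs carry no molecular identifiers, so their number sets only the counting error. No sample and no column of the table was left out.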

Results

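Mouse neural cortical stem cells are neural progenitors, here kept undifferentiated in a medium with FGF4, EGF and heparin. They were sequenced with or without incubation with extracellular vesicles (EVs), the membrane particles that cells release into their medium. The labels state an incubation of about 24 h for the EV samples. The EVs came from cells of the placental lineage. Those of mouse trophoblast stem cells (mTSCs) were collected at day 2 of culture. Those of parietal trophoblast giant cells (pTGCs), the large invasive cells formed from mTSCs, were collected at day 6 of differentiation with retinoic acid per the growth protocol, while a treatment label calls these pTGCs undifferentiated. The 12 samples comprised 4 with no EVs, 4 with mTSC EVs and 4 with pTGC EVs, for which mRNA was measured as read pairs per gene. The labels do not say that the replicates of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The labels state no vehicle and no incubation time for the no EV samples.

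The libraries held 45.2 to 58.3 M (mega) assigned read pairs, with group means of 54.7 ± 3.57 M for no EV, 50.7 ± 4.78 M for mTSC EV and 54.7 ± 4.34 M for pTGC EV (SD, n = 4). No EV replicate 3 stood apart from the other 11 libraries in genes with a count and in nuclear-retained RNA. It had the most read pairs but the fewest genes with a count, 26526 against 28305 to 29466. It was also low in 10 RNAs that stay mostly in the nucleus, such as Malat1, Xist and Kcnq1ot1, with a mean of 3.49 log2 CPM against 4.66 to 4.71 in the other no EV libraries and 4.61 to 5.18 in the EV libraries. Kcnq1ot1 was at 5.53 CPM in this library and at 30.2 to 34.7 CPM in the other no EV libraries. Mitochondrially encoded transcripts made up 2.27 ± 0.182% of the counts with no EV, 2.87 ± 0.197% with mTSC EV (exact permutation p = 0.0286, adjusted p = 0.171 over 15 tests of the libraries) and 2.72 ± 0.263% with pTGC EV (p = 0.0571, adjusted p = 0.171). The smallest p this design allows is 0.0286, and none of the 15 tests passed after adjustment.

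**Figure D1:**
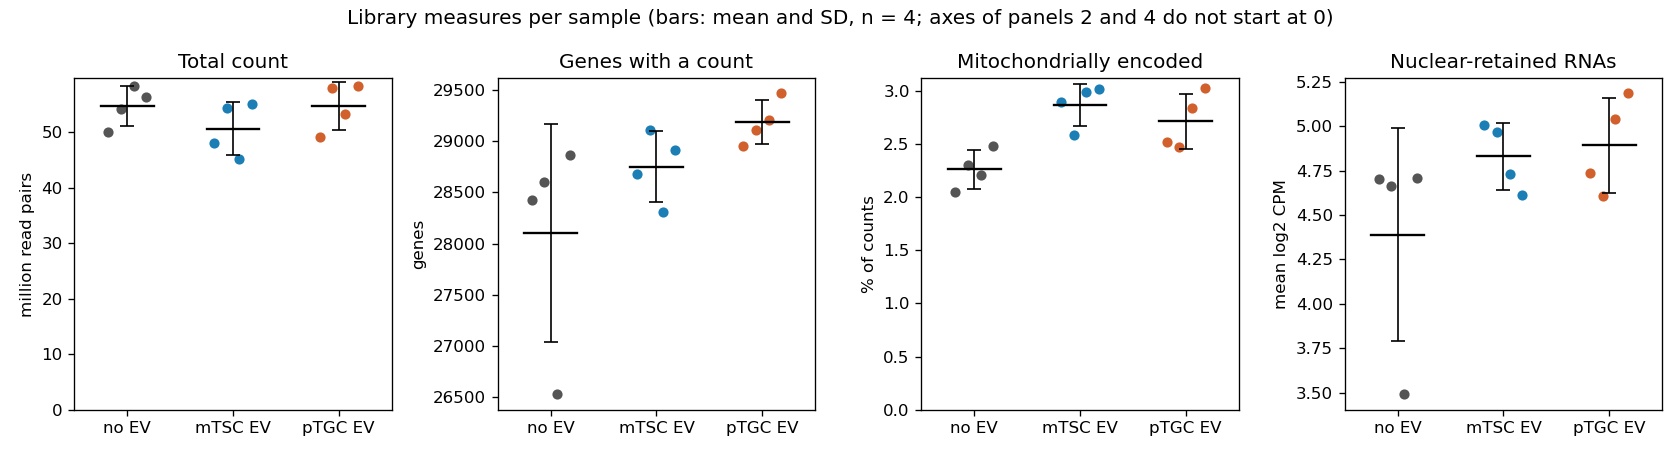
Each point is 1 of the 12 libraries, by group on the horizontal axis. The panels give the total in M read pairs, the number of genes with a count, the percentage of counts from mitochondrially encoded genes and the mean log2 CPM of 10 nuclear-retained RNAs, and the axes of the panels for genes and nuclear-retained RNAs do not start at 0. No EV replicate 3 has 58.3 M read pairs, 26526 genes and a nuclear-retained RNA level of 3.49.

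The comparison of mTSC EV with no EV asks which mRNA levels of the neural stem cells differ after a day with vesicles of undifferentiated trophoblast. With mTSC EVs, 320 genes were higher and 623 lower of the 19213 tested. The median absolute log2 fold change of these 943 genes was 0.22, and 78 of them differed by more than 1.5-fold. Abca1 (ENSMUSG00000015243.5, GRCm39 chromosome 4, 53030787 to 53159895), which exports cholesterol from cells, rose 1.75-fold, from 5.47 ± 0.624 to 9.59 ± 1.24 CPM (SD, n = 4, log2 fold change 0.81, SE 0.12, adjusted p = 0.0039). Pfkl (ENSMUSG00000020277.11, chromosome 10, 77822781 to 77845917), a phosphofructokinase of glycolysis, fell to 0.671 times the no EV level, from 72.5 ± 6.21 to 48.7 ± 1.11 CPM (SD, n = 4, log2 fold change -0.57, SE 0.05, adjusted p = 0.00018). Pdk1 (ENSMUSG00000006494.12, chromosome 2, 71703568 to 71734202), a kinase that holds pyruvate out of the mitochondrial citric acid cycle, fell to 0.566 times, from 15.2 ± 3.16 to 8.58 ± 0.872 CPM (SD, n = 4, log2 fold change -0.82, SE 0.13, adjusted p = 0.00544).

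Among the other largest increases that the rule could name were Hlf (1.54-fold, adjusted p = 0.0022), a transcription factor driven by the circadian clock, the FGF receptor Fgfr2 (1.52-fold, adjusted p = 0.0107), the transcriptional repressor Zbtb16 (1.48-fold, adjusted p = 0.0109) and Ccdc78 (1.56-fold, adjusted p = 0.021). The sodium pump subunit Atp1a2 and the retinaldehyde-binding protein gene Rlbp1 fell to 0.647 and 0.669 times the no EV level (adjusted p = 0.0301 and 0.0184).

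Camera placed 7 of the 28 tested lists above or below the other genes. Lower with mTSC EVs were glycolysis and hypoxia (adjusted p = 0.0214), DNA replication and G1/S (0.00877), cholesterol biosynthesis (0.00877) and nuclear oxidative phosphorylation (0.00636), and higher were mitochondrially encoded genes (0.00101), axon guidance and synapse (0.0214) and p53 targets (0.0214). None of the 7 held with an estimated correlation (adjusted p = 0.796 for each with an estimated correlation, 1 list at an unadjusted p under 0.05), nor with fry, which called 0 lists (6 at an unadjusted p under 0.05). Of 22 glycolysis and hypoxia genes, 4 fell, among them Pfkl (-0.57), Pdk1 (-0.82) and the collagen hydroxylase P4ha1 (-0.28) as log2 fold changes, and 18 did not pass. Adjusted over the list alone, 2 were higher and 7 lower. Of 22 DNA replication and G1/S genes, 4 fell, including the polymerase subunit Pola1 (-0.17) and the licensing factor Cdt1 (-0.19), and 18 did not pass, with 5 lower when adjusted over the list alone. Of 24 cholesterol biosynthesis genes, 3 fell, including Dhcr7 (-0.26) and Ebp (-0.22), enzymes of the late steps, and 21 did not pass, with 8 lower adjusted over the list alone. Of 26 nuclear genes of oxidative phosphorylation, 2 fell, Ndufs1 (-0.13) and Sdha (-0.12), and 24 did not pass, with the same count adjusted over the list alone. No EV replicate 3, low in nuclear-retained RNA, was among the 4 controls. Without it, 3 of the glycolysis genes fell, no member of the other 3 lower lists passed, and the camera calls ended (adjusted p = 0.0671 for glycolysis, replication and oxidative phosphorylation and 0.159 for cholesterol). With nuclear-retained RNA as a covariate, none of the 4 lower calls held (adjusted p = 0.264 for glycolysis, 0.382 for replication and cholesterol and 0.494 for oxidative phosphorylation).

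Among the higher lists, 6 of 13 mitochondrially encoded genes rose, including mt-Cytb (0.39) and mt-Nd1 (0.35), and 7 did not pass, while 7 were higher adjusted over the list alone. Of 31 axon guidance and synapse genes, 3 rose and 28 did not pass. These were the ephrin receptor Ephb1 (0.38), the semaphorin Sema6a (0.19) and the synaptic adhesion gene Lrrtm2 (0.41), and 4 were higher adjusted over the list alone. Of 20 p53 targets, only Mdm2 (0.23), the ubiquitin ligase that acts on p53, rose and 19 did not pass, with 6 higher and 1 lower adjusted over the list alone. Without no EV replicate 3, whose nuclear-retained RNA was low, 1 mitochondrially encoded gene, 1 axon guidance gene and 1 p53 target were higher, and the 3 camera calls held (adjusted p = 0.00092, 0.0189 and 0.0297).

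Outside these lists, Sox3 (-0.28) and Hes1 (-0.19), transcription factors of neural progenitors, fell, and the other 17 neural stem cell and radial glia genes did not pass (1 higher and 3 lower adjusted over the list alone). Gclc (0.27), the first enzyme of glutathione synthesis, was among 3 of 20 oxidative stress and NRF2 genes that rose, while 1 fell (5 and 3 adjusted over the list alone). Sesn2 (0.21) and the amino acid transporter Slc7a5 (0.28) were among 3 of 25 genes of the unfolded protein response and ATF4 that rose, with 3 higher and 4 lower adjusted over the list alone. In the extracellular matrix list fibronectin, Fn1 (0.31), rose and 2 of 26 fell, among them the brain proteoglycan Ncan (-0.33), with 3 higher and 2 lower adjusted over the list alone. No member of the lists for neurons (16 tested), mitosis and G2/M (22), retinoic acid targets (12) or ribosomal proteins (30) passed, over all genes or adjusted over the list alone. In the lists for astrocytes, interferon-stimulated genes and Notch 1 gene fell in each, in those for NF-kB, FGF and Wnt 1 gene rose in each, 2 TGF-beta and BMP targets rose, 2 lysosomal and 2 vesicle and endosome genes fell, and in the oligodendrocyte list 1 rose and 1 fell. Adjusted over the list alone, 3 astrocyte and 3 vesicle and endosome genes were lower, 2 Notch genes were higher and 1 lower, 1 gene was higher and 1 lower in both the NF-kB and FGF lists, and the counts of the other lists were the same. Without no EV replicate 3 and its low nuclear-retained RNA, 2 oxidative stress and 2 unfolded protein response genes were higher, and no gene passed in the astrocyte, oligodendrocyte, NF-kB, TGF-beta and BMP, lysosome and vesicle lists. The median and the mean or test differed in sign for the astrocyte, retinoic acid and TGF-beta and BMP lists.

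Differences came from the edgeR test on 4 samples against 4. The 943 calls dropped to 224 without no EV replicate 3, of which 222 were among the 943, to 137 without mTSC EV replicate 3, to 386, 437 and 369 without no EV replicates 1, 2 and 4, and to 516, 478 and 597 without mTSC EV replicates 1, 2 and 4. The groups did not overlap in CPM for 3158 genes (16.4%), where chance gives 2.86%. Of the 29 genes named here that passed, 14 passed under every alternative, namely Abca1, Hlf, Fgfr2, Zbtb16, Pdk1, Pfkl, Sox3, Hes1, Ephb1, Mdm2, Gclc, Sesn2, Fn1 and Ncan. The other 15 lost the call without mTSC EV replicate 3 (adjusted p 0.0509 to 0.138), and 12 of them without no EV replicate 3 (0.0507 to 0.196), 10 without no EV replicate 4 (0.0501 to 0.0829), 9 without no EV replicate 1 (0.0577 to 0.0869), 7 without no EV replicate 2 (0.0526 to 0.0868), 7 without mTSC EV replicate 1 (0.0525 to 0.122), 6 without mTSC EV replicate 2 (0.0528 to 0.113) and 5 without mTSC EV replicate 4 (0.0553 to 0.0861). Leaving out mTSC EV replicate 1 ended the camera calls for replication, oxidative phosphorylation and axon guidance (adjusted p = 0.0589 for each) and glycolysis (0.0849). Leaving out no EV replicate 2 ended those for axon guidance (0.123) and p53 (0.055), and mTSC EV replicate 2 that for p53 (0.0536).

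The comparison of pTGC EV with no EV asks the same of vesicles of pTGCs. With pTGC EVs, 1054 genes were higher and 1692 lower of the 19213 tested. The median absolute log2 fold change of these 2746 genes was 0.23, and 422 differed by more than 1.5-fold. Ubc (ENSMUSG00000008348.10, GRCm39 chromosome 5, 125463029 to 125467266), which encodes a chain of ubiquitin units, fell to 0.529 times the no EV level, from 129.5 ± 6.11 to 68.5 ± 4.11 CPM (SD, n = 4, log2 fold change -0.92, SE 0.04, adjusted p = 3.36e-08). Fbxo32 (ENSMUSG00000022358.8, chromosome 15, 58039275 to 58078328), a ubiquitin ligase subunit known from muscle atrophy, fell to 0.523 times, from 14.5 ± 0.401 to 7.61 ± 1.28 CPM (SD, n = 4, log2 fold change -0.93, SE 0.09, adjusted p = 4.95e-05). Vwa5b1 (ENSMUSG00000028753.13, chromosome 4, 138292671 to 138363195) rose 1.90-fold, from 15.8 ± 0.548 to 30.1 ± 2.82 CPM (SD, n = 4, log2 fold change 0.93, SE 0.06, adjusted p = 2.17e-06).

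Among the genes that the rule could name, the largest increases were less even between libraries. The retinoic acid receptor gene Rarb (ENSMUSG00000017491.10, chromosome 14, 5650540 to 6038924) rose 2.38-fold (SE 0.33 on the log2 scale, adjusted p = 0.0221), with 38.4% of its exonic bases shared with other genes and not counted. It was at 16.1, 4.22, 4.51 and 12.5 CPM in pTGC EV replicates 1 to 4 against 3.91 ± 0.0864 CPM with no EV (SD, n = 4). Ephb2, an ephrin receptor of axon guidance, rose 2.30-fold (log2 fold change 1.20, SE 0.29, adjusted p = 0.0143), with 88.6, 28.1, 28.4 and 75.6 CPM in the pTGC EV replicates and 22.7 to 25.3 CPM with no EV. Sorcs2, a receptor for proneurotrophins, rose 2.35-fold (log2 fold change 1.23, SE 0.39, adjusted p = 0.0462), and Pacsin1, an endocytosis protein of neurons, rose 2.13-fold (log2 fold change 1.09, SE 0.18, adjusted p = 0.00198). Without no EV replicate 3, Rarb and Sorcs2 did not pass (adjusted p = 0.0505 and 0.100), and all of Rarb, Sorcs2 and Ephb2 lost the call without pTGC EV replicate 4. Atp1a2 and Pdk1 fell to 0.519 and 0.562 times the no EV level (adjusted p = 0.00137 and 0.00128).

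**Figure D2:**
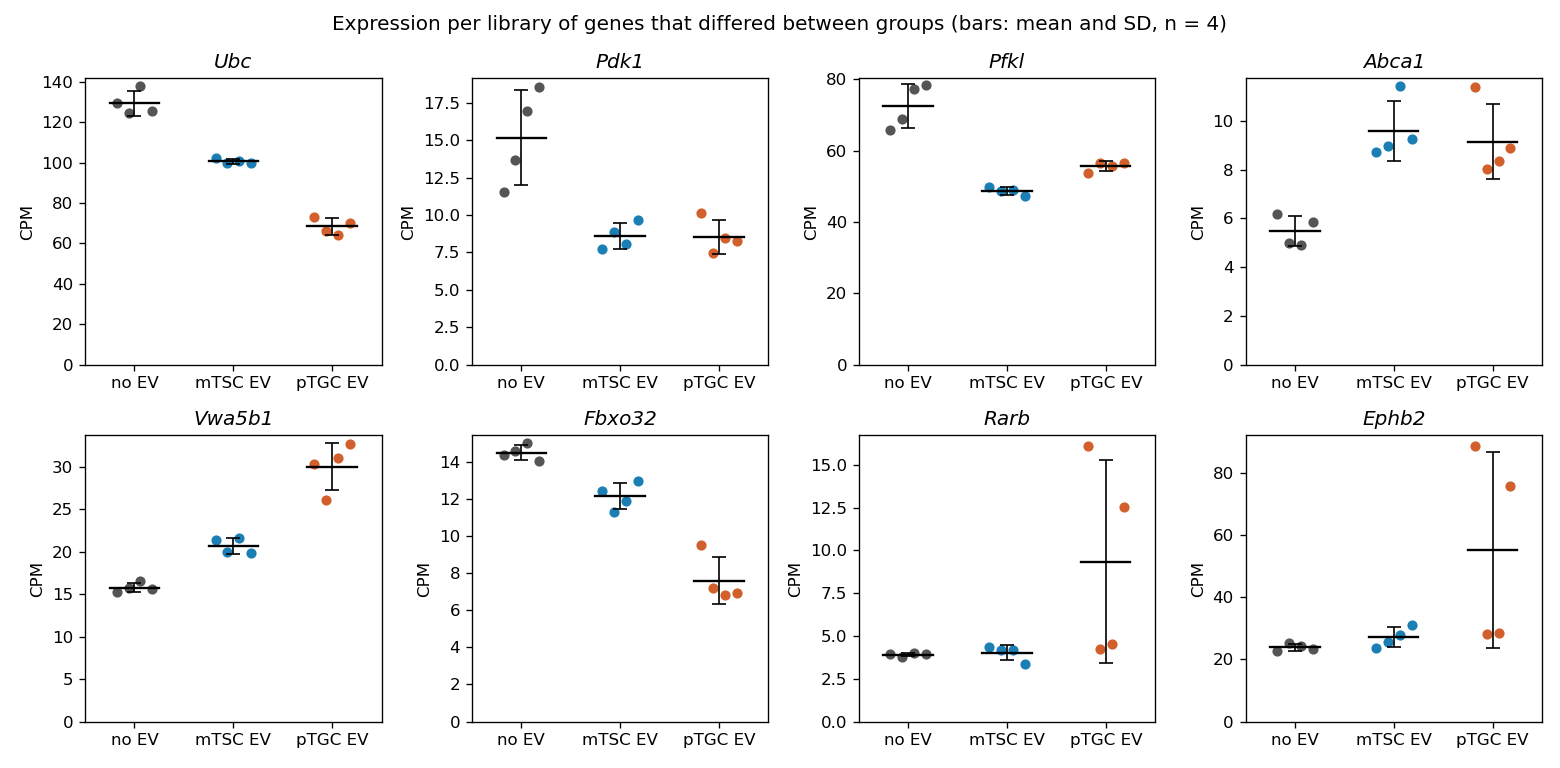
Each panel gives 1 gene, with its level in CPM on the vertical axis and the groups no EV, mTSC EV and pTGC EV on the horizontal axis. Points are libraries and bars are the mean with its SD (n = 4). Mean Ubc falls from 129.5 with no EV to 68.5 CPM with pTGC EV, and the 4 pTGC EV libraries spread from 4.22 to 16.1 CPM for Rarb.

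Camera placed 8 lists above or below the other genes with pTGC EVs. Lower were lysosome and autophagy (adjusted p = 0.00383), extracellular vesicle and endosome (0.0229), nuclear oxidative phosphorylation (0.00107), cholesterol biosynthesis (0.0431) and glycolysis and hypoxia (0.0468), and higher were mitochondrially encoded genes (0.000905), axon guidance and synapse (0.0325) and mitosis and G2/M (0.0401). None of the 8 held with an estimated correlation (adjusted p = 0.618 to 0.681 with an estimated correlation, 0 lists at an unadjusted p under 0.05), whereas fry called 8 lists, 5 of them among these. Of 22 lysosome and autophagy genes, 8 fell, including the sialidase Neu1 (-0.28) and the proton pump subunit Atp6v1h (-0.18), and 14 did not pass, with 10 lower adjusted over the list alone. Of 24 genes of extracellular vesicles and endosomes, 7 fell, including Vps4a (-0.22) and Hgs (-0.20), which sort cargo into multivesicular bodies, and 17 did not pass, with 1 higher and 9 lower adjusted over the list alone. Of 24 cholesterol biosynthesis genes, 5 fell, including Ebp (-0.24) and Pmvk (-0.22), and 19 did not pass, with 1 higher and 6 lower adjusted over the list alone. Of 22 glycolysis and hypoxia genes, 5 fell, including Pdk1 (-0.83) and Pfkl (-0.38), and 17 did not pass, with 2 higher and 7 lower adjusted over the list alone. Of 26 nuclear oxidative phosphorylation genes, Ndufs1 (-0.13) fell and 25 did not pass, also when adjusted over the list alone. Without no EV replicate 3, the library low in nuclear-retained RNA, the numbers lower were 1 for lysosome, 4 for vesicles and endosomes, 2 for cholesterol, 2 for glycolysis and 0 for oxidative phosphorylation. Camera calls then ended for vesicles and endosomes (adjusted p = 0.0687), cholesterol (0.439) and glycolysis (0.0859). None of the 5 lower calls held with nuclear-retained RNA as a covariate (adjusted p = 0.193 for lysosome, 0.301 for vesicles and endosomes and for glycolysis, 0.296 for oxidative phosphorylation and 0.766 for cholesterol).

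**Figure D3:**
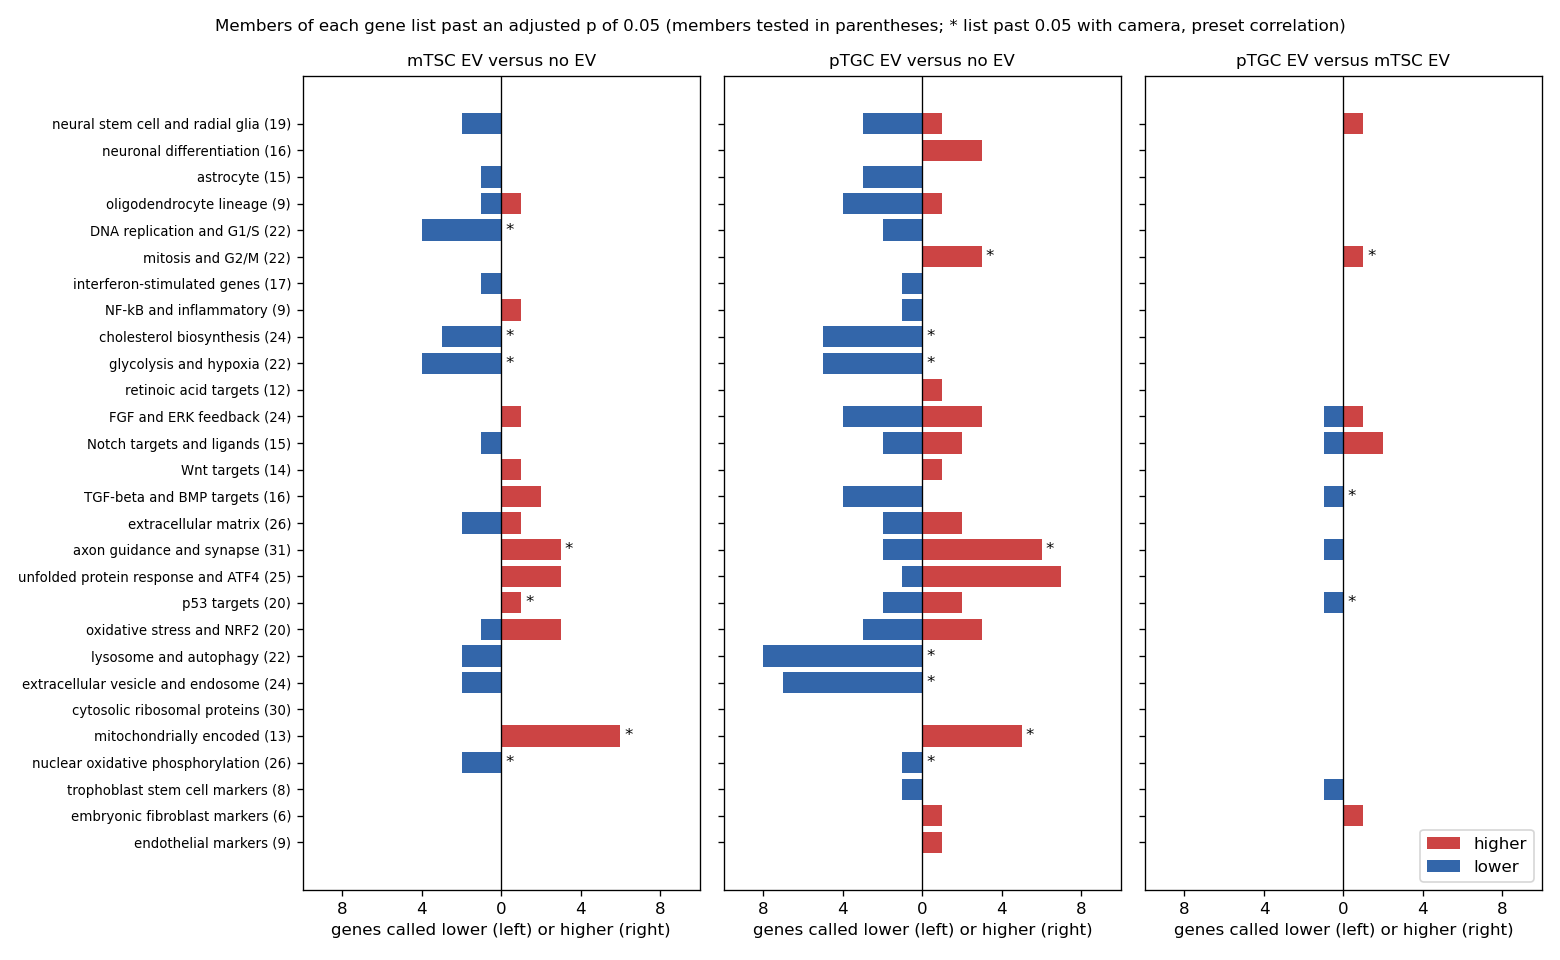
Bars give, for each tested gene list on the vertical axis, the number of members higher (to the right) and lower (to the left) at an adjusted p below 0.05, with 1 panel for each of the 3 comparisons. An asterisk marks a list that camera placed above or below the other genes with the preset correlation. The lysosome list has 8 members lower with pTGC EV, and 6 mitochondrially encoded genes are higher with mTSC EV.

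Of 13 mitochondrially encoded genes, 5 rose, including mt-Nd5 (0.37) and mt-Co2 (0.32), and 8 did not pass, with 9 higher adjusted over the list alone. Of 31 axon guidance and synapse genes, 6 rose, including Ephb1 (0.35) and the semaphorin receptor Plxna2 (0.24), 2 fell, including the Slit receptor Robo2 (-0.21), and 23 did not pass, with 8 higher and 2 lower adjusted over the list alone. Of 22 mitosis genes, 3 rose, including the kinase Aurka (0.23) and the kinesin Kif23 (0.35), and 19 did not pass, with 4 higher adjusted over the list alone. With no EV replicate 3 and its low nuclear-retained RNA left out, 3 mitochondrially encoded genes, 5 axon guidance genes and 3 mitosis genes were higher, and these camera calls held (adjusted p = 0.000959, 0.0168 and 0.0168).

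Other lists had members that passed without a camera call. Of 25 genes of the unfolded protein response and ATF4, 7 rose, including the pseudokinase Trib3 (0.66) and Slc7a5 (0.39), and 1 fell, with the same counts adjusted over the list alone. That list was called without no EV replicate 3 (adjusted p = 0.0168, against 0.175 with all libraries). Among 15 Notch genes, the feedback inhibitor Nrarp (0.44, with 79.4% of its exonic bases shared with another gene) was 1 of 2 that rose, and the ligands Dll1 (-0.38) and Dll3 (-0.74) fell, as they did adjusted over the list alone. The neuronal genes Gap43 (0.36) and Ncam1 (0.24) were among 3 of 16 that rose, also adjusted over the list alone, although the median log2 fold change of that list was -0.03 against a mean of 0.04 and a test pointing up. Sox3 (-0.38) and the glutamate transporter gene Slc1a3 (-0.21) were among 3 of 19 neural stem cell genes that fell, and 1 rose (4 and 2 adjusted over the list alone). Both subunits of the glutathione synthesis enzyme, Gclc (0.33) and Gclm (0.19), were among 3 oxidative stress and NRF2 genes that rose, and 3 fell, also adjusted over the list alone. Of 24 FGF and ERK feedback genes, 3 rose and 4 fell (3 and 7 adjusted over the list alone), 4 of 16 TGF-beta and BMP targets fell (7), and of the glial lists 3 of 15 astrocyte genes fell (3), and 1 of 9 oligodendrocyte genes rose and 4 fell (1 and 5). Of the p53 targets and of the extracellular matrix genes 2 rose and 2 fell, 2 replication genes and 1 interferon-stimulated and 1 NF-kB gene fell, 1 Wnt target and 1 of 12 retinoic acid targets, Rarb, rose, and no ribosomal protein gene passed. Adjusted over the list alone, 4 p53 targets were higher and 3 lower, 1 NF-kB gene was higher and 1 lower, no replication gene passed, and the counts of the other lists were the same. Leaving out no EV replicate 3, low in nuclear-retained RNA, left 1 FGF and ERK feedback gene, 1 TGF-beta and BMP target, 2 neural stem cell genes, 3 oligodendrocyte genes and 1 p53 target lower, and 2 neuronal genes and 1 p53 target higher. No oxidative stress, unfolded protein response, replication or interferon-stimulated gene was then lower, and no retinoic acid target higher. The median and the mean or test also differed in sign for the p53, oxidative stress and fibroblast lists, none of them called.

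The edgeR test called 1439 genes without no EV replicate 3, of which 1394 were among the 2746. The count was 1345 without pTGC EV replicate 3, 1397 without pTGC EV replicate 4 and 2097 to 3247 without any 1 of the other 5 libraries. For 3822 genes (19.9%) the groups did not overlap in CPM, where chance gives 2.86%. Of the 37 genes named here that passed, 28 did so under every alternative. The other 9 were Rarb, Sorcs2, Ephb2, Ebp, Atp6v1h, mt-Co2, mt-Nd5, Ndufs1 and Fbln2, all of which lost the call without pTGC EV replicate 4 (adjusted p 0.0507 to 0.108), 5 of them without no EV replicate 3 (0.0505 to 0.101), 4 each without no EV replicate 2 (0.0512 to 0.108), pTGC EV replicate 1 (0.053 to 0.151) and pTGC EV replicate 3 (0.0557 to 0.106), and 3 each without no EV replicate 1 (0.0671 to 0.0972) and no EV replicate 4 (0.0558 to 0.114). Camera calls ended without pTGC EV replicate 4 for axon guidance, vesicles and endosomes and oxidative phosphorylation (adjusted p = 0.0601 for each), cholesterol (0.0922) and glycolysis (0.0787), without no EV replicate 2 for axon guidance and mitosis (0.0684 for both), and without no EV replicate 4 for axon guidance (0.0592), glycolysis and mitosis (0.076 for both). They also ended without pTGC EV replicate 1 for cholesterol (0.179), replicate 2 for mitosis (0.122) and replicate 3 for glycolysis (0.0912).

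The comparison of pTGC EV with mTSC EV asks whether the vesicles of both trophoblast cell types left the neural cells with different mRNA levels. It found 48 genes higher and 75 lower with pTGC EVs, with a median absolute log2 fold change of 0.28 and 9 genes beyond 1.5-fold. Ubc was lower with pTGC EVs, at 68.5 ± 4.11 against 100.6 ± 1.10 CPM (SD, n = 4, log2 fold change -0.56, SE 0.04, adjusted p = 2.53e-05). Vwa5b1 was 1.45-fold higher (log2 fold change 0.54, SE 0.06, adjusted p = 0.000856). Fbxo32 and Pdp1, a phosphatase that activates the pyruvate dehydrogenase complex, were lower, at 0.624 and 0.63 times the mTSC EV level (adjusted p = 0.0025 and 0.000778).

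Also lower with pTGC EVs were Mir6236 (-0.64), the stress-induced gene Gadd45g (-0.61), the BMP target Id2 (-0.58) and the clock gene Per1 (-0.57), as log2 fold changes. Mir6236 is a microRNA annotation of 123 exonic bases, not an mRNA, and the source of its reads was not tested. The early response gene Ier3 (0.44), Nrarp (0.44) and the NMDA receptor subunit gene Grin2a (0.43) were higher. Camera placed mitosis and G2/M genes higher (adjusted p = 4.32e-06) and p53 targets (0.0031) and TGF-beta and BMP targets (0.0101) lower. These 3 calls were lost with an estimated correlation (adjusted p = 0.398 for each with an estimated correlation, 2 lists at an unadjusted p under 0.05), and fry called 2 lists, both among the 3. Of 22 mitosis genes, Aurka (0.27) was higher and 21 did not pass, with 4 higher adjusted over the list alone. Of 20 p53 targets, Trp53inp1 (-0.24) was lower and 19 did not pass, with 1 higher and 6 lower adjusted over the list alone. Of 16 TGF-beta and BMP targets, Id2 was lower and 15 did not pass, with 4 lower adjusted over the list alone. In the Notch list, Hes1 (0.24) and Nrarp were higher and Dll1 (-0.36) lower among 15 (2 and 3 adjusted over the list alone). Of the other lists, 1 FGF gene was higher and 1 lower, 1 axon guidance gene was lower, Hes1 was the 1 neural stem cell gene that was higher, and apart from 1 trophoblast and 1 fibroblast marker no member of the remaining lists passed over all genes. Adjusted over the list alone, 4 oligodendrocyte, 1 astrocyte and 1 lysosomal gene were lower, 1 neuronal gene was higher and 1 lower, and 1 gene was higher in each of the glycolysis, retinoic acid and unfolded protein response lists. The median and the test differed in sign for the cholesterol, glycolysis, mitochondrially encoded, Wnt and fibroblast lists, and the median and the mean for the neuronal list, none of which camera called.

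This edgeR comparison of 4 samples with 4 had 1374 genes (7.15%) without overlap of the groups, where chance gives 2.86%. The 123 calls dropped to 44, 67 and 50 without mTSC EV replicates 1, 2 and 3 and to 50 and 59 without pTGC EV replicates 3 and 4, and 115 of them passed without no EV replicate 3, which only enters the shared spread. Of the 17 named genes that passed, 8 passed under every alternative, and Ier3, Nrarp, Grin2a, Gadd45g, Aurka, Trp53inp1, Sox21, Fbln2 and Mir6236 each lost the call without at least 1 library. Counting by library, 8 lost it without mTSC EV replicate 1 (adjusted p 0.0525 to 0.116), 5 without replicate 2 (0.0527 to 0.129), 5 without replicate 3 (0.0562 to 0.163) and 2 without replicate 4 (0.0525 to 0.0619), and 2, 4, 4 and 7 without pTGC EV replicates 1, 2, 3 and 4 (0.0661 to 0.0736, 0.0672 to 0.0731, 0.0558 to 0.143 and 0.0501 to 0.12).

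Both EV groups were compared with the same 4 no EV samples, which by itself makes their fold changes alike. Across the tested genes, the covariance of the log2 fold changes was 0.0672. The values for no effect were 0.0161 in simulations of unchanged groups with shared controls (highest of 100, 0.0169) and 0.0269 computed from the spread of the controls themselves. When each EV group was given its own pair of controls, the observed covariance was 0.0422 on average (0.0379 to 0.0484 over 6 assignments). That is a measured value without shared controls, not one for no effect. With no EV replicate 3 left out and the controls shared, the covariance was 0.0387, against 0.0165 for no effect from the spread of the other 3 controls. The jackknife standard error over the libraries was 0.0472. Of the genes called, 200 were higher with both kinds of EV, where independent lists of these sizes give 17.6, and 473 were lower with both, where independent lists give 54.9. In the simulations of unchanged groups at most 1 gene was called with both, since hardly any gene is called there. The same numbers of top-ranked genes in those simulations overlapped by 129.6 on average for higher (115 to 147) and 249.2 for lower (222 to 281), from the shared controls alone. The simulations drew each gene separately, without a deviation of a whole library like that of no EV replicate 3. They can therefore understate the overlap that shared controls give. With the controls divided, 7 to 22 genes were higher with both, against 0.246 to 0.764 for independent lists, and 5 to 35 were lower with both, against 0.246 to 1.07. Only 3 genes were called in opposite directions, the clock gene Arntl (0.20 with mTSC EVs and -0.16 with pTGC EVs, as log2 fold changes), Id2 (0.32 and -0.26) and the transcription factor Elf1 (0.29 and -0.20). Arntl and Elf1 were outside the rule for named genes and were chosen after their values were seen.

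Markers of the cells that could have come along with the vesicles were measured in the same libraries. The 20 trophoblast stem cell markers, 8 of them tested and some also expressed by neural progenitors, summed to 431.3 ± 12.8 CPM with no EV, 410.2 ± 16.6 with mTSC EV and 393.7 ± 9.47 with pTGC EV (SD, n = 4). Sox21, also a neural gene, fell with pTGC EVs (-0.42) and was lower than with mTSC EVs (-0.26), as the only member to pass (2 lower adjusted over the list alone against no EV, 3 against mTSC EV). Ddah1 and Ets2 did not pass, with log2 fold changes of -0.09 and 0.07 for mTSC EV and -0.14 and 0.15 for pTGC EV against no EV. The 25 giant cell markers, 1 of them tested, summed to 1291 ± 48.6, 1432 ± 244 and 1543 ± 138 CPM in the same order, nearly all of it from the imprinted gene Peg10, which neural cells express (0.14 with adjusted p = 0.354, and 0.24 with adjusted p = 0.0949). Embryonic fibroblast markers, relevant because the vesicles were collected in fibroblast-conditioned medium, summed to 282.9 ± 6.64, 277.4 ± 4.44 and 314.4 ± 11.9 CPM. The sums of the marker lists were not tested and, unlike the levels of single genes, not TMM-scaled. Of the fibroblast markers Fbln2 rose with pTGC EVs (0.11 against no EV and 0.18 against mTSC EV), while Prrx1 and Acta2 had 0.29 and 0.24 against no EV (adjusted p = 0.086 and 0.185). Microglial markers summed to 2.73, 3.36 and 3.11 CPM and endothelial markers to 10.1, 10.2 and 11.3 CPM, with 1 endothelial gene higher with pTGC EVs against no EV.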

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

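All tests of explanations in this part were chosen after the result was seen, while the regroupings of the samples with all libraries were planned.

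Other groupings of the samples were tried for each count. For genes, the real grouping gave 943, 2746 and 123 for mTSC EV against no EV, pTGC EV against no EV and pTGC EV against mTSC EV, and the highest of the other 34 groupings gave 0, 0 and 13. In each comparison 1 of 35 groupings, the real one, reached the real count. That is the smallest share this design can give, before any adjustment over the comparisons, so chance is unlikely but not excluded. A difference between cultures or extractions, which the labels leave open, could also single out the real grouping. For gene lists, the real grouping gave 7, 8 and 3, the highest other gave 9 in each comparison, and 6, 9 and 30 of 35 groupings gave as many, so chance cannot be excluded. With no EV replicate 3 left out, the real groupings gave 224 and 1439 genes against a highest other of 0 and 978. Again 1 of 35 was as large in both, with the same limits. The grouping with 978 genes put pTGC EV replicate 2 with the controls, which points to a structure of the samples beyond the groups.

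No EV replicate 3 was far from the other 3 no EV libraries in nuclear-retained RNA, at 3.49 against 4.66 to 4.71 log2 CPM. Against those libraries its genes below -1 log2 CPM were lower by a median log2 difference of -0.416 and those above 7 log2 CPM higher by 0.0628. Shallower sequencing is argued against by its 58.3 M read pairs, the most of any library. This library alone, or a trend with nuclear-retained RNA over all libraries, might account for the many genes that differed, but 224 genes with mTSC EVs and 1439 with pTGC EVs passed without it, and 421 and 1362 with that RNA as a covariate, which argues against either as the whole cause. Within groups that RNA varied mainly through no EV replicate 3 (SD 0.60 log2 CPM with no EV, 0.19 with mTSC EV and 0.27 with pTGC EV). The covariate therefore hardly tests a trend among the other libraries. It remains open whether RNA quality, the extraction or the cells set no EV replicate 3 apart, since no value measured these, and a response to EVs stays open as an untested biological difference for the rest.

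In 15 of 225 groups of 4 libraries screened, 1 library lay far from the other 3, where chance gives about 1 in 20. Genes of the same library are not independent, so this rate is only a guide. On the axis of second-largest variation between all libraries (10.8% of the variance), mTSC EV replicate 4 was at -32.9 and the other mTSC EV libraries at 1.77 to 12.0. On that axis pTGC EV replicate 1 was at -22.1 and the other pTGC EV libraries at 2.16 to 8.86. Both libraries thus departed from their groups beyond single genes. In mTSC EV replicate 4, levels were 10.957 CPM for Zbtb16 (others 8.22 to 8.63), 3.54 CPM for Atp1a2 (5.73 to 6.07), 7.73 CPM for Rlbp1 (11.6 to 12.2), 1811 CPM for Peg10 (1295 to 1325), 75.3 CPM for Sorcs2 (22.8 to 24.9) and 147.9 CPM for Gap43 (109.9 to 114.0). In pTGC EV replicate 1, they were 31.4 CPM for Hlf (27.7 to 28.3), 43.8 CPM for Ets2 (33.7 to 34.7) and 9.51 CPM for Fbxo32 (6.80 to 7.20). Lrrtm2 was at 4.43 CPM in pTGC EV replicate 2 (3.50 to 3.64). In no EV replicate 2, Atp1a2 was at 7.16 CPM (8.49 to 8.67) and Peg10 at 1356 CPM (1275 to 1285). In no EV replicate 3, Slc7a5 was at 273.5 CPM (231.5 to 236.3) and Gclm at 99.5 CPM (93.8 to 94.1).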

How the results depend on the processing

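All alternatives were planned, except the covariate for nuclear-retained RNA and leaving out no EV replicate 3 for pTGC EV against mTSC EV (155 genes), which were chosen after the data had been seen. Counts are given for mTSC EV against no EV, pTGC EV against no EV and pTGC EV against mTSC EV, in that order. Numbers of genes stayed within 1.5 times of 943, 2746 and 123 with DESeq2's size factors (784, 2482 and 126), the 1 CPM filter (1025, 2492 and 159) and limma-voom (866, 2809 and 112). They moved further for mTSC EV against no EV with the DESeq2 test (1563), the replicate block (420) and the covariate (421), for pTGC EV against no EV with the covariate (1362), and for pTGC EV against mTSC EV without a filter (252), with the DESeq2 test (374), with only the 2 groups (46), with the block (57) and with the covariate (270). Fewer samples estimate the spread in the fit of 2 groups, and for the others the cause was not tested. The replicate numbers did not pair the samples, since deviations from the group mean correlated by -0.24 to 0.18 and 2 of 12 samples were closest to those of their own number, so the block removes degrees of freedom without removing a shared effect.

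Leaving out each library in turn gave 137 to 597, 1345 to 3247 and 44 to 173 genes. The share of called genes that were higher rose from 33.9% to 48.2% with mTSC EVs and from 38.4% to 49.3% with pTGC EVs when no EV replicate 3 was left out, to 43.7% and 50.1% with the 1 CPM filter, and to 53.3% and 52.8% with no filter, where most called genes were higher with either kind of EV. The covariance of both sets of fold changes ranged from 0.0387 without no EV replicate 3 to 0.0972 without no EV replicate 4, and was 0.0671 with DESeq2's size factors and 0.0327 with the 1 CPM filter.

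Camera's 7, 8 and 3 lists became 7, 8 and 3 with DESeq2's size factors, 6, 6 and 3 with the 1 CPM filter, 7, 7 and 3 with the block and 4, 4 and 3 with the covariate, which left 0 of the lower calls against no EV in either EV group. An estimated correlation left 0, 0 and 0 lists, with 1, 0 and 2 at an unadjusted p under 0.05, and fry called 0, 8 and 2. The estimated correlation widens the null and fry asks another question, and for the covariate the cause was not tested. Leaving out each library gave 3 to 10, 3 to 9 and 3 to 8 lists.

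No named gene that passed changed direction under any alternative. For pTGC EV against mTSC EV, the uncalled log2 fold change of Ets2 (0.08) ranged from -0.0197 without pTGC EV replicate 1 to 0.149 over the left-out libraries, and that of Prrx1 (0.05) from -0.0317 without mTSC EV replicate 1 to 0.218, also below 0 without pTGC EV replicate 1. The cause was not tested. Depth limits genes near the floor: in simulated data, recovery of 1.5-fold changes was 50.0% over all tested genes and 100% at 5 CPM or more.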

Other observations

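The lists and all tests in this part were chosen after the results were seen.

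Genes of the circadian clock differed with both kinds of EV. With mTSC EVs, 7 of 18 tested clock genes rose and 11 did not pass (10 higher adjusted over the list alone), namely Hlf (0.62), Per2 (0.49), Dbp (0.33), Tef (0.33), Cry1 (0.27), Rora (0.26) and Arntl (0.20), as log2 fold changes with 4 samples per group. When no EV replicate 3, low in nuclear-retained RNA, was left out, 4 passed. Camera placed the list higher (adjusted p = 6.74e-05, and adjusted p = 0.419 with an estimated correlation). With pTGC EVs, 7 rose, among them Hlf (0.65), Per3 (0.47) and Dbp (0.44), and 3 fell, Per1 (-0.37), Bhlhe40 (-0.25) and Arntl (-0.16), with 7 higher and 5 lower adjusted over the list alone, 6 and 2 without no EV replicate 3, and no camera call (adjusted p = 0.318). Between the EVs, Per1 (-0.57), Rora (-0.41) and Arntl (-0.36) were lower with pTGC EVs, and camera placed the list lower (adjusted p = 0.00859, and 0.385 as adjusted p with an estimated correlation).

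The list of heat shock chaperones and their partners also holds the ubiquitin genes Ubc and Ubb, which are not chaperones. Some of its members fell. With mTSC EVs, 5 of 18 tested genes fell, Ubc (-0.36), Hsph1 (-0.34), Hspa8 (-0.24), Ahsa1 (-0.24) and Stip1 (-0.20), the cochaperone Bag3 rose (0.22), and 12 did not pass (1 higher and 9 lower adjusted over the list alone). With pTGC EVs 6 fell, those 5 (Ubc -0.92, Hspa8 -0.46, Hsph1 -0.36, Ahsa1 -0.25, Stip1 -0.16) and Dnaja1 (-0.23), and 12 did not pass (0 higher and 7 lower adjusted over the list alone). Camera placed the list, with Ubc in it, lower in both (adjusted p = 6.28e-05 and 9.88e-06), with adjusted p = 0.599 and 0.616 with an estimated correlation. The fall of Ubc had been seen before the list was written, so these calls are no independent support. In the absence of no EV replicate 3, low in nuclear-retained RNA, 3 and 5 fell. The 10 tested nuclear-retained RNAs themselves had a median log2 fold change of 0.37 with mTSC EVs, where none passed, and 0.43 with pTGC EVs, where Snhg14 rose (0.51, adjusted p = 0.0482, and 0.089 without no EV replicate 3; 0 with mTSC EVs and 5 with pTGC EVs higher adjusted over the list alone). These medians were 0.15 and 0.22 without no EV replicate 3. Camera placed the list higher in both (adjusted p = 0.0166 and 0.0169), with adjusted p = 0.733 and 0.630 with an estimated correlation.

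One candidate explanation for the clock genes is that the samples were collected at another phase of the clock, in which Arntl moves against its targets. With mTSC EVs, Arntl rose with its 4 called targets (0.20, SE 0.05, adjusted p = 0.036), unlike this prediction. The labels state 1 incubation time, for the EV samples alone, and clock genes may stand at different points of their cycles. The rise of Arntl therefore cannot exclude a shift. The log2 fold change of Arntl was 0.19 without no EV replicate 3, with fewer samples and no call (adjusted p = 0.0824). With nuclear-retained RNA as a covariate it was 0.16, also without a call (adjusted p = 0.119). With pTGC EVs, Arntl moved against most targets (-0.16, SE 0.05, and adjusted p = 0.0806 without no EV replicate 3), while Per1, 1 of 7 called targets, moved against the others. A shift of phase therefore cannot be told apart from another change, with 1 time stated and none for the no EV samples. A trend with the share of nuclear-retained RNA is argued against as the whole cause, since 4 of 7 clock genes with mTSC EVs and 9 of 10 with pTGC EVs passed with it as a covariate. That RNA varied within groups mainly through no EV replicate 3, so a trend among the other libraries was hardly tested. A response to EVs, the biological difference the design names, stays open and untested.

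For the chaperones, less heat or protein-folding stress might lower them. The strongly heat-inducible Hspa1a, Hspa1b, Dnajb1 and Bag3 had median log2 fold changes of -0.0507 with mTSC EVs and -0.122 with pTGC EVs. For the other 14 tested genes of the list, Ubc and Ubb among them, the median was -0.13 in both comparisons. The differences were 0.08 (SE 0.08) and 0.01 (SE 0.07), so this explanation stays open. These SEs treat the genes as independent, although all were measured in the same libraries (estimated correlation between genes of the list 0.27). With mTSC EVs, Bag3 rose (0.22, SE 0.06, adjusted p = 0.0490, and 0.25 with adjusted p = 0.0824 and no call without no EV replicate 3) and Dnajb1 hardly moved (-0.03, SE 0.04), while an exact permutation of the 18 genes, which leaves out their SE, depended on its definition (p = 0.0176 by the doubled tail and 0.180 by the absolute difference, and 0.825 and 0.949 with pTGC EVs). A trend with the share of nuclear-retained RNA is argued against as the whole cause, since 4 of 5 and 5 of 6 list genes called lower, Ubc among them, passed with the covariate. As for the clock genes, a trend among libraries other than no EV replicate 3 was hardly tested. A response to EVs stays open, untested.

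Giant cell transcripts in the treated cells could be RNA carried by the pTGC EVs. The 24 giant cell markers other than Peg10 had 34 counts in the no EV group, 47 in the mTSC EV group and 72 in the pTGC EV group, and the 13 prolactin-family genes, abundant in giant cells, had 2, 2 and 5 counts. The highest count of a prolactin-family gene over the 4 pTGC EV libraries was 2. Multi-mapping reads were not counted, so reads shared between similar genes of the family would be missing. The counts therefore cannot decide whether these mRNAs were transferred. Psg17, a pregnancy-specific glycoprotein gene, took most of the rise, with 8, 14 and 34 counts, or 0.0358 ± 0.0251 CPM with no EV and 0.153 ± 0.0746 CPM with pTGC EV (SD, n = 4, two-sided exact permutation p = 0.0286 before adjustment, the smallest this design can give). Plac1 had 23, 29 and 32 counts (exact permutation p = 0.486). Whether EVs carried the Psg17 RNA or the cells made it cannot be told apart. Rarb, itself induced by retinoic acid, was higher with pTGC EVs, whose source cells were grown with it, so retinoic acid carried over from the pTGC culture might raise it. Its rise was uneven between the 4 pTGC EV libraries, as given above, and its call was lost under 6 of 16 alternatives. None of the other 11 tested retinoic acid targets passed in edgeR, and the highest of them, Dhrs3, had a log2 fold change of 0.75 (0.754, adjusted p = 0.198) at 0.42 against 0.249 CPM, so this cannot be told apart from another cause.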
